A study of Homo sapiens with 6 samples.

How the data were processed

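RNA from 6 samples of HN12 cells, 3 labelled as treated with DMSO and 3 with CPI-613, was extracted with TRIzol after 24 h, made into libraries with a NEBNext Ultra II kit from total RNA and sequenced on a DNBSEQ instrument, per the labels' protocols. The submitters' processing notes name CASAVA, STAR 2.5, HTSeq, edgeR 3.16.5, DESeq2 and the build hg38, without stating what each was used for. Whether reads were counted by strand and which annotation release was used are not given in the sources used here. The dose of CPI-613 is likewise not given in the sources used here.

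The first deposited table holds estimated counts per RefSeq transcript for 79031 protein-coding transcripts of 16330 genes, made by the authors with a counter that is not named for this table. Its values are mostly not whole, as when reads shared by transcripts are split between them, although 87.8% of the sums per gene were whole within 0.03. The second deposited table holds values per gene whose unit is not named. They were taken as FPKM, counts that the authors divided by transcript length in kilobases and by library total before deposit, because over 1139 genes with a single transcript the FPKM worth of 1 read followed the inverse of the library's total count within 0.6%. In 27 transcripts the cell of CPI-613 replicate 1 holds a day and month in place of a number, the form a spreadsheet gives to some values. Those 27 transcripts were left out in all libraries, which removed 3 genes, ZNF865, CACNA1S and LOC112268076, and lowered the counts of others, such as THBS3. Mitochondrially encoded genes and noncoding RNAs were not analysed here.

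Estimated counts were summed per gene and rounded to whole numbers. The 53 genes without a symbol took 0.016% of the counts. Genes were filtered with edgeR's filterByExpr (a minimum count of 10 in enough libraries and 15 in total), scaled by TMM, and tested with edgeR 4.0.16's quasi-likelihood functions for CPI-613 against Control, in both directions and with group as the one covariate. Benjamini-Hochberg adjustment covered all 12671 genes tested, at a threshold of 0.05. The standard error of a log2 fold change was taken as its size over the square root of the F statistic. CPM use the TMM-scaled library size. No library pair agreed within counting noise, since the chi-square per degree of freedom between pairs was at least 3.88, the value for Control replicates 1 and 3.

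Gene lists, 38 with 1075 entries, were written before the data were examined, from the title of the series, the known targets of CPI-613 and the markers of squamous carcinoma and other cell types. Of these, 36 had at least 3 tested genes and entered camera of limma 3.58.1, with a preset correlation of 0.01 between genes, on log2 CPM with a prior count of 2, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move, on balance, one way and does not compare them with other genes. Members of a list were also adjusted over the list alone.

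The genes named in the text followed a rule fixed with the lists. It took 13 genes chosen for the study's question (THBS2, THBS1, CD47, CD36, DLAT, PDHA1, OGDH, DLST, HSPA5, DDIT3, ATF4, ATF3 and XBP1), the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 2 and no overlap between the groups, and from each list up to 4 called members with the largest changes, or up to 2 with the highest CPM where none was called. PTPRC, LONP1, and the leukocyte markers and gene families of the closing section, were chosen after their values were seen. Coordinates come from NCBI's RefSeq table for GRCh38 patch 14, the build that hg38 names, matched by gene identifier.

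The depth was 11531949 to 15486514 counts per library. The 10 most abundant genes took 4.65% to 7.76% of the counts of a library. The spread between libraries exceeded counting error in every pair, so precision rests on the 3 libraries per group.

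Alternatives fixed with the lists were other scalings (the DESeq2 median of ratios, upper quartile, library size only), no filter or a mean count of at least 10, DESeq2 1.42.0, limma-voom, a block for the replicate number, leaving out each library, an adjusted p of 0.01, other set tests and a prior count of 0.5. Added after seeing the data were offsets that remove each library's trend of log2 CPM on GC content, alone or with transcript length, fitted by loess with a span of 0.3, the same with libraries left out, leaving out Control replicate 2 and CPI-613 replicate 3 together, and reading the day-month cells as days of the year. GC content and length came from the longest protein-coding GENCODE 29 transcript of each gene, matched for 12600 tested genes (99.44%).

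The scripts were tested on simulated counts with the library sizes of this comparison and its means and spread after the GC and length trends were removed. With the observed GC and length trends added to the simulation, the edgeR test without offset recovered 0% of 98 genes changed 2-fold and 38.4% of 99 genes changed 4-fold, and with the offset 57.1% and 96% among 12578 genes, with 10 calls of unchanged genes with the offset and 0 without. Without such trends both fits recovered 61.6% of 99 genes at 2-fold and 98% of 100 genes at 4-fold among 12588 genes. Analyses used R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.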

Results

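HN12, a human head and neck squamous cell carcinoma line, was grown with the solvent DMSO (Control) or with CPI-613 for 24 h, and RNA was sequenced from 3 libraries per group. CPI-613 (devimistat) is a lipoate analogue directed against the mitochondrial pyruvate and 2-oxoglutarate dehydrogenase complexes, which feed and form part of the tricarboxylic acid (TCA) cycle. The deposited table of estimated counts summed to 11531949, 12508548 and 12171791 in Control replicates 1 to 3. It summed to 13458518, 13896440 and 15486514 in CPI-613 replicates 1 to 3. In each library 12293 to 12707 genes had at least 10 counts. The labels do not state that the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

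The comparison of CPI-613 with Control addressed how the transcriptome of HN12 cells differs after 24 h with this compound, with THBS2 and endoplasmic reticulum (ER) stress named in the title of the series. Whether the TCA cycle was blocked in these cultures was not measured here. With CPI-613, 21 of 39 genes of the ATF4 stress response, 13 of 24 of cholesterol synthesis and uptake, 6 of 17 of fatty acid synthesis and 15 of 27 of the immediate early response were called higher. Of 45 interferon-stimulated genes 11 were called lower. Camera, which compares a list with all other genes, called these lists, with adjusted p of 0.11 to 0.19 with an estimated correlation. FGF19, a secreted growth factor, rose from 0.466 ± 0.083 to 37.5 ± 14.1 CPM (counts scaled to library size; mean ± SD, n = 3), and KRT13, a keratin of stratified epithelia, fell from 119 ± 24.9 to 0.718 ± 0.561 CPM. Of 12671 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05, 246 were higher and 157 lower with CPI-613, and 397 of these 403 genes changed at least 2-fold. In all 403, every CPI-613 library lay beyond every Control library. Over all tested genes 1501 lay above and 1162 below in this way, 21%, where 10% is the average over all splits of interchangeable libraries. Genes that move together can exceed this average without a group effect, and the share was not taken for the other splits. Of the calls 61% were higher, and 46.9% when scaled by library size only, which moved the median log2 fold change of all genes from 0.02 to -0.17.

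The number of called genes depended on single libraries. No gene was called without Control replicate 1 or without Control replicate 3 (1064 and 1118 genes at an unadjusted p under 0.05, and 413 and 404 calls by DESeq2). By edgeR 7 were called without CPI-613 replicate 2, 219 without Control replicate 2, 657 without CPI-613 replicate 3 and 905 without CPI-613 replicate 1. Libraries of the same group differed along the GC content of the transcripts, as the plot of deviation by GC content shows. After each library's trend on GC content and transcript length was removed, a correction chosen after seeing the data and called GC- and length-adjusted from here on, 789 genes were higher and 681 lower. These included 396 of the 403 genes, all in the same direction. Under this correction 590 genes were called without Control replicate 1, 615 without Control replicate 3, 589 without CPI-613 replicate 2 and 2603 without CPI-613 replicate 1.

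**Figure D1:**
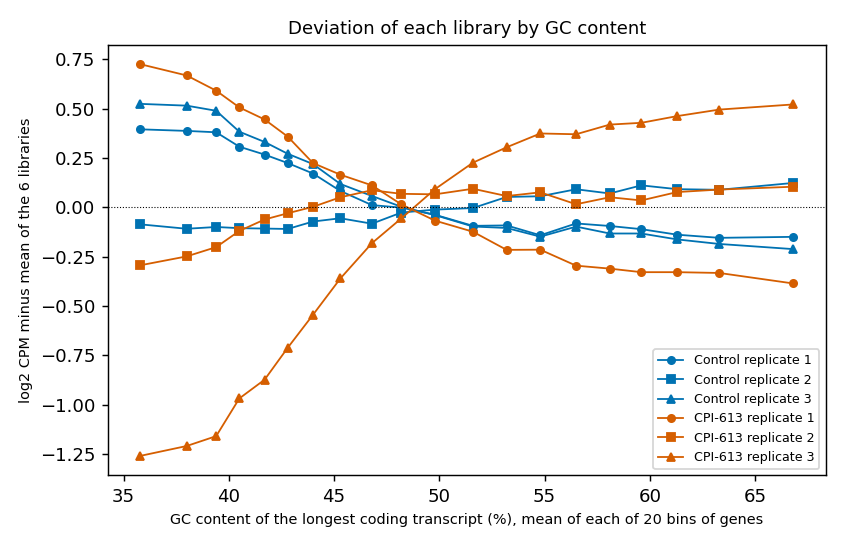
Mean deviation of each library's log2 CPM from the mean of the 6 libraries (y axis, log2 units) against the GC content of the genes' longest coding transcript (x axis, percent), in 20 bins of genes; blue lines are Control, orange lines CPI-613 libraries, and symbols give the replicate number. In the bin with the lowest GC content CPI-613 replicate 1 lay at 0.725 and CPI-613 replicate 3 at -1.26, and Control replicates 1 and 3 ran apart from Control replicate 2.

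THBS2 (gene ID 7058) encodes thrombospondin-2, a secreted matricellular glycoprotein, and lies on chromosome 6 at 169215785 to 169253846 (GRCh38). Its transcripts measured 158 ± 23.3 CPM in Control and 89 ± 13.5 CPM with CPI-613 (SD, n = 3), with each CPI-613 library below each Control library. The log2 fold change of -0.83 (SE 0.20) did not pass edgeR's quasi-likelihood test over all genes (Benjamini-Hochberg adjusted p = 0.0894). The GC- and length-adjusted value was -0.93 (SE 0.17) and passed the same edgeR test (Benjamini-Hochberg adjusted p = 0.0146, with 0.0133 to 0.426 over the alternatives). That call ended without Control replicate 1 or Control replicate 3, where the adjusted p was 0.0757 and 0.0709. THBS1, the related thrombospondin-1 on chromosome 15 at 39581079 to 39599466, measured 802 ± 266 and 369.5 ± 69.3 CPM. Its log2 fold change of -1.12 (SE 0.28) did not pass either (edgeR, Benjamini-Hochberg adjusted p = 0.0973, with 0.013 to 0.257 over the alternatives); it passed with DESeq2 and when adjusted for GC content alone.

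Among thrombospondins and their receptors, 0 of 14 tested members were called by edgeR over all genes. Adjusted over the list alone, 2 members were higher and 3 lower; 3 were higher and 4 lower at an unadjusted p under 0.05, 1 higher and 3 lower by DESeq2, and 0 by limma-voom. The receptor CD47 measured 130 ± 18.1 and 93.7 ± 12.5 CPM (log2 fold change -0.47, SE 0.19), and this value turned to 0.28 (SE 0.42) when GC- and length-adjusted. ITGA3, an integrin subunit, measured 1386 ± 228 and 2502 ± 598 CPM, was not called, and passed when GC- and length-adjusted (edgeR, Benjamini-Hochberg adjusted p = 0.00764, with 0.00764 to 0.589 over the alternatives). CD36, a thrombospondin and fatty acid receptor, had 2, 3 and 7 reads in Control replicates 1 to 3 and 0, 2 and 1 reads in CPI-613 replicates 1 to 3, too few to test. The list's median log2 fold change was -0.01. Camera did not call it (Benjamini-Hochberg adjusted p = 0.95).

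Of 39 tested genes of the ATF4 integrated stress response 21 rose with CPI-613, none fell and 18 were not called. The median log2 fold change was 1.42, and all 39 estimates lay above 0. CHAC1, which degrades glutathione, rose from 3.41 ± 1.56 to 67.6 ± 27.8 CPM. TRIB3, a pseudokinase that binds ATF4, rose from 36.1 ± 10.7 to 301 ± 99.9 CPM, GDF15, a stress cytokine, from 19.1 ± 0.739 to 145 ± 42.2 CPM, and CTH, a cysteine-forming enzyme, from 9.11 ± 1.21 to 67.2 ± 3.42 CPM. DDIT3, which encodes CHOP, rose by 1.88 (SE 0.19) and ATF3 by 2.24 (SE 0.26) on the log2 scale (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0072 and 0.00943). ATF4 itself measured 491 ± 76.8 and 981 ± 196 CPM, a log2 fold change of 1.00 (SE 0.22) that did not pass over all genes (edgeR, Benjamini-Hochberg adjusted p = 0.0679). The GC- and length-adjusted value was 0.81 (SE 0.11) and passed (edgeR, Benjamini-Hochberg adjusted p = 0.00436, with 0.00371 to 0.371 over all alternatives). Camera called the list higher (Benjamini-Hochberg adjusted p = 9.7e-27), a call lost at an adjusted p = 0.11 with an estimated correlation. Adjusted over the list alone, 32 members were higher, and 33 members were higher over all genes when GC- and length-adjusted.

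Of 38 tested ER chaperones and genes of ER-associated degradation 3 rose, none fell and 35 were not called, with a median log2 fold change of 0.41, and 5 were higher adjusted over the list alone. XBP1, a transcription factor of the unfolded protein response, rose from 142 ± 16.8 to 472 ± 78.2 CPM. ERN1, the ER sensor that splices XBP1 RNA, rose from 24.7 ± 1.10 to 82.6 ± 6.62 CPM, and HERPUD1, an ER degradation factor, from 53.4 ± 6.38 to 136 ± 17.6 CPM (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p between 0.0072 and 0.0159 for the 3 genes). HSPA5, the ER chaperone BiP, measured 1808 ± 72.6 and 3652 ± 627 CPM; its log2 fold change of 1.01 (SE 0.21) missed the threshold (edgeR, Benjamini-Hochberg adjusted p = 0.0505), and the GC- and length-adjusted 1.05 (SE 0.10) passed it (edgeR, Benjamini-Hochberg adjusted p = 0.00162, with 0.00101 to 0.315 over all alternatives). CALR, the ER lectin calreticulin, measured 1598 ± 94.8 and 1476 ± 520 CPM and was not called. Camera called the list higher (Benjamini-Hochberg adjusted p = 8e-06), with an adjusted p = 0.25 with an estimated correlation, and 14 members were higher when GC- and length-adjusted.

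**Figure D2:**
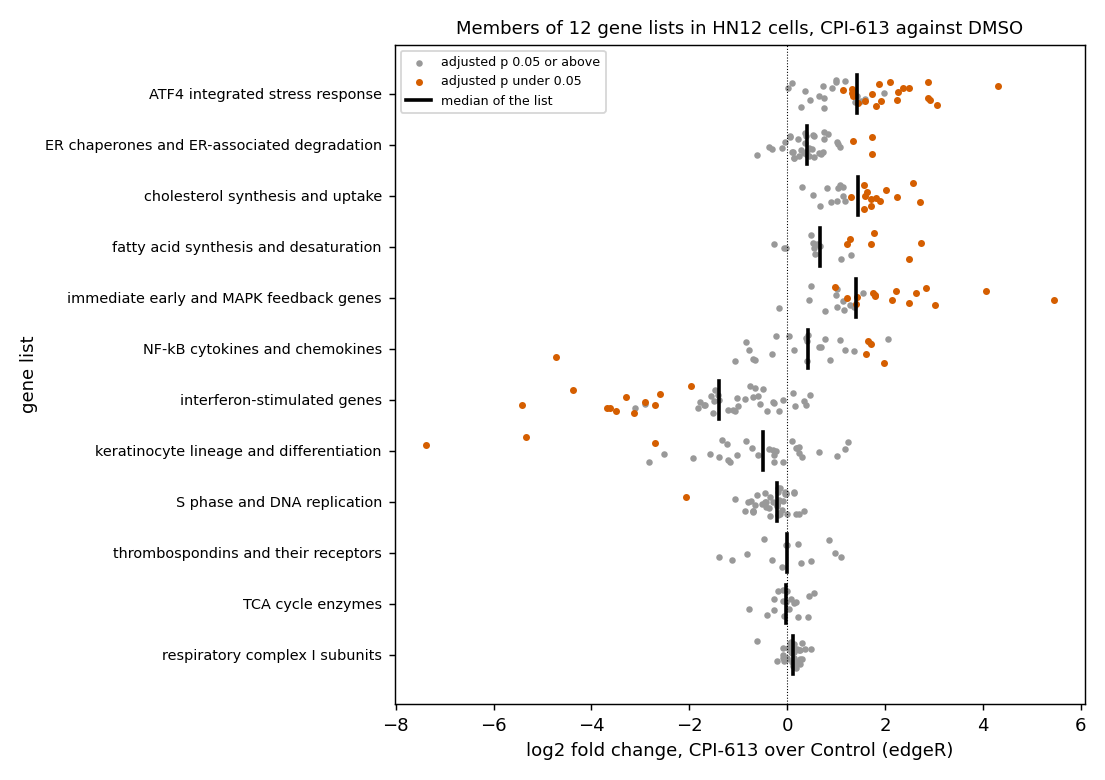
log2 fold changes of CPI-613 over Control by edgeR (x axis) for the tested members of 12 gene lists (y axis); each point is a gene, orange where the adjusted p over all genes was under 0.05, and black bars are list medians. In the ATF4 list 21 of 39 members were called higher, in the interferon list 11 of 45 were called lower, and in the TCA cycle list 0 of 18 were called.

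Of 24 genes of cholesterol synthesis and uptake 13 rose, none fell and 11 were not called. All 24 estimates were above 0, with a median log2 fold change of 1.44. INSIG1, a sterol sensor, rose from 23.1 ± 4.33 to 138 ± 27.3 CPM, and DHCR7, the last enzyme of cholesterol synthesis, from 254 ± 26.8 to 1033 ± 336 CPM. HMGCS1, an early enzyme of the mevalonate pathway, rose from 229 ± 84.1 to 1092 ± 490 CPM, a log2 fold change of 2.25 (SE 0.45) close to the threshold (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0457). HMGCS1 missed the threshold in the 3 other scalings, at an adjusted p of 0.0533 to 0.0912 (6.27e-05 to 0.208 over all alternatives). Camera called the list higher (Benjamini-Hochberg adjusted p = 1.3e-17; adjusted p = 0.11 with an estimated correlation), and 19 members were higher adjusted over the list alone and 22 when GC- and length-adjusted. Of 17 tested genes of fatty acid synthesis and desaturation 6 rose, none fell and 11 were not called. SCD, the stearoyl-CoA desaturase, rose from 979 ± 232 to 6507 ± 1747 CPM, ACSS2, an acetyl-CoA synthetase, from 45.4 ± 6.51 to 253 ± 66 CPM, and FASN, the fatty acid synthase, from 705 ± 62.2 to 2308 ± 752 CPM. This list had a median log2 fold change of 0.67 and was called higher by camera (Benjamini-Hochberg adjusted p = 1.6e-07; adjusted p = 0.15 with an estimated correlation), with 8 members higher adjusted over the list alone and 12 when GC- and length-adjusted. Of 28 genes of fatty acid oxidation and PPAR targets 26 were not called. ANGPTL4, a lipoprotein lipase inhibitor, rose from 20.1 ± 7.21 to 83 ± 25.3 CPM, FABP5, a fatty acid binding protein, fell from 189 ± 42.6 to 76 ± 11.4 CPM. Adjusted over the list alone 1 was higher and 1 lower (camera, Benjamini-Hochberg adjusted p = 0.11, and 0.041 without CPI-613 replicate 1). With an estimated correlation and all libraries camera gave an adjusted p = 0.84.

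Of 27 immediate early and MAPK feedback genes 15 rose, none fell and 12 were not called, with a median log2 fold change of 1.41. EGR3, an immediate early transcription factor, rose from 0.310 ± 0.281 to 14 ± 4.88 CPM and EGR2 from 0.926 ± 0.528 to 15.7 ± 3.04 CPM. The EGF receptor ligands HBEGF and AREG rose from 48.2 ± 9.06 to 391 ± 31.2 CPM and from 142 ± 26 to 1009 ± 146 CPM. Camera called the list higher (Benjamini-Hochberg adjusted p = 6.8e-22; adjusted p = 0.11 with an estimated correlation), and 22 members were higher adjusted over the list alone and 20 over all genes when GC- and length-adjusted. Of 27 tested NF-kB cytokines and chemokines 4 rose, 1 fell and 22 were not called, and 11 were higher and 4 lower adjusted over the list alone. IL11, a cytokine of the IL-6 family, rose from 14.5 ± 4.25 to 57.5 ± 15.8 CPM and the neutrophil chemokines CXCL2 and CXCL3, which are close paralogs, from 26.9 ± 8.49 to 88.3 ± 8.76 CPM and from 4.70 ± 1.11 to 14.9 ± 3.11 CPM. CCL2, a monocyte chemokine, fell from 4.91 ± 0.684 to 0.176 ± 0.119 CPM. The median of this list was 0.42, and camera called it higher (Benjamini-Hochberg adjusted p = 0.0073; adjusted p = 0.41 with an estimated correlation).

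Of 45 tested interferon-stimulated genes 11 fell with CPI-613, none rose and 34 were not called. The median log2 fold change was -1.40, and 40 of the 45 estimates lay below 0. GBP2, an interferon-induced GTPase, fell from 25.5 ± 10.7 to 2.92 ± 0.626 CPM, RSAD2 (viperin), an antiviral enzyme, from 6.43 ± 4.34 to 0.299 ± 0.127 CPM. CMPK2, a mitochondrial nucleotide kinase, fell from 5 ± 1.29 to 0.383 ± 0.285 CPM and IFI44L from 3.80 ± 1.94 to 0.299 ± 0.063 CPM. CXCL10, an interferon-induced chemokine, fell from 2.52 ± 1.30 to 0.0475 ± 0.0823 CPM (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p between 0.0133 and 0.0253 for these 5 genes). Control replicate 2 lay nearest to the CPI-613 libraries in these 5 genes, with 13.7 CPM of GBP2 against 28.3 and 34.6 and 2.1 CPM of RSAD2 against 6.4 and 10.8 in Control replicates 1 and 3. Adjusted over the list alone, 25 members were lower, and 28 were lower over all genes when GC- and length-adjusted. Camera called the list lower (Benjamini-Hochberg adjusted p = 1e-16; adjusted p = 0.19 with an estimated correlation).

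Antigen presentation genes of MHC class I gave no call by edgeR among 19 tested members, with 2 lower at an unadjusted p under 0.05 and 0 called by DESeq2, by limma-voom or adjusted over the list alone. Camera did not call the list (Benjamini-Hochberg adjusted p = 0.12). It called it lower without CPI-613 replicate 3 (0.00073), when scaled by library size only (0.025) and when GC- and length-adjusted (0.002, with 0.00053 to 0.98 over the alternatives; adjusted p = 0.75 with an estimated correlation). In that last fit 6 members were lower. HLA-C measured 1120 ± 21.9 and 1248 ± 429 CPM. Of 17 immune checkpoint ligands and T-cell-suppressive genes 1 rose and 16 were not called, the one being ARG2, a mitochondrial arginase, from 15.5 ± 2.002 to 56.9 ± 4.94 CPM, and 2 were higher and 3 lower adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.84).

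Of 32 tested keratinocyte lineage and differentiation genes 3 fell, none rose and 29 were not called, with 1 higher and 6 lower adjusted over the list alone and a median log2 fold change of -0.48. Besides KRT13, the basal keratin KRT15 fell from 141 ± 30.3 to 21.7 ± 7.83 CPM and KRT1 from 2.38 ± 0.860 to 0.0494 ± 0.0429 CPM. Camera called the list lower (Benjamini-Hochberg adjusted p = 0.00082; adjusted p = 0.74 with an estimated correlation), a call that also ended without CPI-613 replicate 1 at an adjusted p of 0.076. Of 13 tested mesenchymal markers VIM, the intermediate filament vimentin, rose from 46.3 ± 15 to 187 ± 7.86 CPM, 12 were not called, and 1 was higher and 1 lower adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.95).

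Extracellular matrix and matricellular genes went both ways. Of 38 tested members 4 rose, 2 fell and 32 were not called, and 7 were higher and 5 lower adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.51). LAMB3, a basement membrane protein, rose from 1710 ± 178 to 5643 ± 883 CPM. TIMP3, a metalloproteinase inhibitor, fell from 80.4 ± 38.7 to 12.3 ± 4.15 CPM and TGFBI, a secreted matrix protein, from 1638 ± 102 to 670.1 ± 195 CPM. TGFBI missed the threshold without the count filter (edgeR, Benjamini-Hochberg adjusted p = 0.051, with 0.000388 to 0.224 over the alternatives). Of 23 TGF-beta response genes 2 rose, 5 fell and 16 were not called, with 7 higher and 7 lower adjusted over the list alone. The inhibitors of DNA binding ID1, ID2 and ID3 fell from 350.1 ± 14.4 to 95.7 ± 42.4 CPM, from 9.51 ± 1.65 to 1.253 ± 0.201 CPM and from 95.5 ± 25 to 11 ± 4.19 CPM, and SMAD6, an inhibitory SMAD, from 5.34 ± 0.829 to 0.248 ± 0.15 CPM. The median of this list was 0.26 while its mean was -0.32 and camera pointed downward without a call (Benjamini-Hochberg adjusted p = 0.93). Fry called it lower (Benjamini-Hochberg adjusted p = 0.015, and 0.0064 when GC- and length-adjusted).

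Genes of the enzymes that CPI-613 is directed against showed no call. Among the 18 TCA cycle enzymes edgeR called 0, with 0 at an unadjusted p under 0.05, 0 by DESeq2 and by limma-voom and 0 adjusted over the list alone. When GC- and length-adjusted, 0 were called and 2 were higher and 1 lower at an unadjusted p under 0.05. OGDH and DLST, of the 2-oxoglutarate dehydrogenase complex, measured 243 ± 38.6 and 354.5 ± 106 CPM and 109 ± 14.4 and 148 ± 22.1 CPM in Control and CPI-613, and SDHA 298 ± 28 and 296 ± 62.9 CPM. Of the 12 tested genes of the pyruvate dehydrogenase complex, its regulators and the pyruvate carriers edgeR called 0, likewise with 0 at an unadjusted p under 0.05, by DESeq2, by limma-voom and adjusted over the list alone. DLAT, its lipoylated subunit, measured 52 ± 5.02 and 48.8 ± 10.6 CPM, PDHA1 47.8 ± 5.29 and 53.1 ± 7.63 CPM, and PDPR 94.3 ± 3.07 and 92.7 ± 8.10 CPM. In the pyruvate dehydrogenase list the GC- and length-adjusted fit called 0, with 1 higher at an unadjusted p under 0.05. Median log2 fold changes were -0.02 for TCA enzymes and 0.02 for the pyruvate dehydrogenase list. The second had a mean of -0.04, and its median turned negative in each of the 3 other scalings (camera, Benjamini-Hochberg adjusted p = 0.95 for both).

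The 12 lipoylation and cuproptosis genes, 37 subunits of respiratory complex I and 35 of complexes III to V had 0 members called by edgeR, 0 at an unadjusted p under 0.05, 0 by DESeq2 and by limma-voom and 0 adjusted over the list alone. The GC- and length-adjusted fit called 0 in each list. At an unadjusted p under 0.05 it gave 1 higher for lipoylation, 1 higher for complex I and 1 lower for complexes III to V. SLC31A1, the copper importer, measured 75.9 ± 1.79 and 86.5 ± 14.3 CPM, NDUFB9 and NDUFV1 of complex I 218 ± 47.2 and 261 ± 69.8 CPM and 181 ± 31.4 and 218 ± 70.4 CPM, and ATP5F1B and COX6A1 788 ± 131 and 860.5 ± 303 CPM and 360.5 ± 65.4 and 395 ± 103 CPM. Median log2 fold changes were -0.04, 0.12 and 0.09, and camera called none of these lists (Benjamini-Hochberg adjusted p = 0.93, 0.68 and 0.95), with camera pointing downward for complexes III to V against the sign of the median. Scaling by library size only turned the medians of both respiratory lists negative, and upper quartile scaling that of complexes III to V. Without CPI-613 replicate 3 the median of complexes III to V was -0.17 and camera called it lower (Benjamini-Hochberg adjusted p = 0.018), and without CPI-613 replicate 1 camera called complex I higher (Benjamini-Hochberg adjusted p = 0.019). Of 14 mitochondrial chaperones and proteases edgeR called 0, with 1 higher at an unadjusted p under 0.05, 1 higher by DESeq2, 0 by limma-voom and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.97). HSPD1 and HSPA9 of that list measured 620.3 ± 31.4 and 462.5 ± 242 CPM and 344 ± 4.86 and 444 ± 123.3 CPM. When GC- and length-adjusted, 2 members were higher. They were LONP1, a protease that measured 117 ± 13.9 and 221.5 ± 62.5 CPM, and HSPA9 (edgeR, Benjamini-Hochberg adjusted p = 0.0491, with 0.0412 to 0.999 over the alternatives).

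PFKFB3, which makes the glycolytic activator fructose 2,6-bisphosphate, fell from 195 ± 24.7 to 62.3 ± 11.8 CPM and was the 1 called gene of 22 tested for glycolysis, with 1 lower adjusted over the list alone. Camera did not call that list (Benjamini-Hochberg adjusted p = 0.25). It called it lower without CPI-613 replicate 3 (0.0033) and when GC- and length-adjusted (0.034, with 0.002 to 0.98 over the alternatives; adjusted p = 0.86 with an estimated correlation). Of 25 hypoxia response genes 3 rose, 1 fell and 21 were not called, with 3 higher and 7 lower adjusted over the list alone. When GC- and length-adjusted, 3 were higher and 6 lower over all genes. The members that rose were VEGFA, an angiogenic factor, from 351 ± 61.6 to 1502 ± 199 CPM, STC2, a secreted glycoprotein, from 216 ± 36.1 to 821 ± 31.9 CPM, and ANGPTL4; VEGFA and STC2 also belong to the ATF4 list. With a median log2 fold change of -0.70 the hypoxia list was called lower by camera (Benjamini-Hochberg adjusted p = 0.013; adjusted p = 0.88 with an estimated correlation), a call that ended without CPI-613 replicate 1, Control replicate 1 or Control replicate 3 at adjusted p of 0.14, 0.066 and 0.096, and when scaled by library size only at 0.06.

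**Figure D3:**
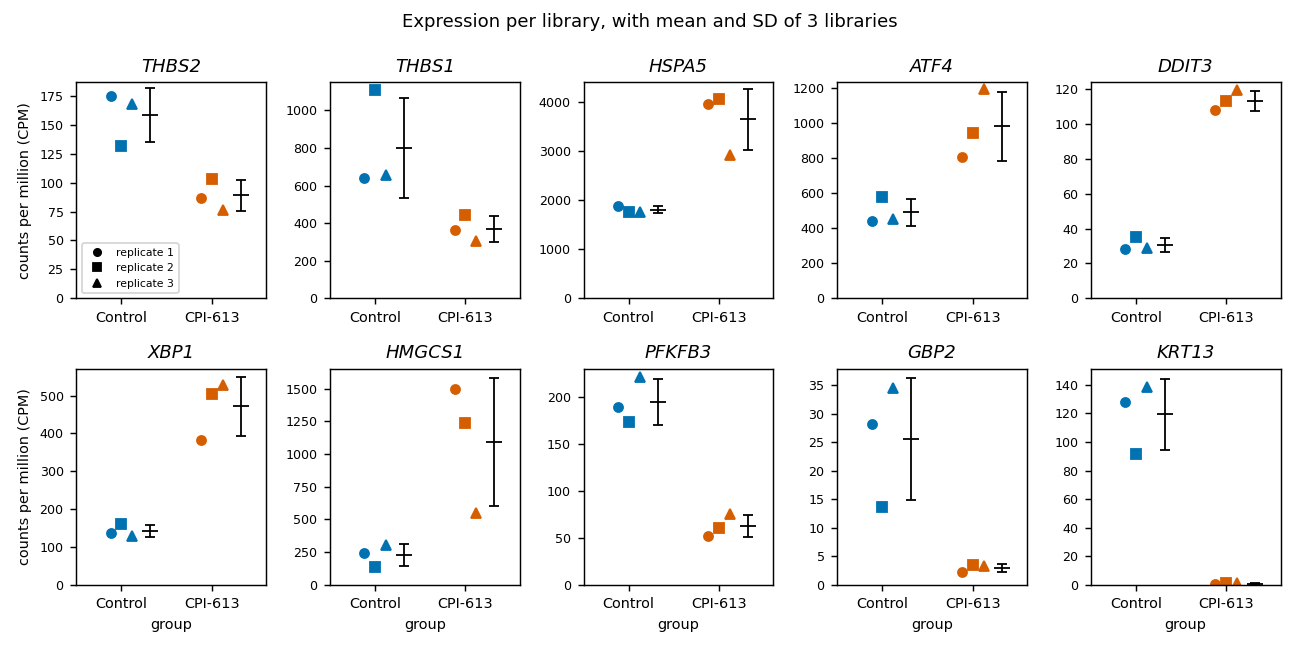
CPM of 10 genes in each library (y axes, from 0), by group (x axis), with circles, squares and triangles for replicates 1, 2 and 3 and black bars for the mean ± SD of 3 libraries. In each of the 10 genes every CPI-613 library lay beyond every Control library, as in THBS2 with 76.6 to 103.3 CPM against 131.5 to 174.9 CPM in Control.

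Of 30 NRF2 antioxidant response genes 2 rose and 28 were not called, with 6 higher and 1 lower adjusted over the list alone. When GC- and length-adjusted, 10 were higher over all genes. SLC7A11, the cystine importer shared with the ATF4 list, rose from 21.8 ± 0.679 to 104 ± 66.9 CPM, close to the threshold (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0498), and missed it in the other scalings, where the adjusted p of SLC7A11 was 0.0606 to 0.0991 (0.000111 to 0.24 over all alternatives). AKR1C1, an aldo-keto reductase whose reads may be shared with near-identical paralogs, rose from 3.62 ± 0.998 to 11.2 ± 0.549 CPM and missed the threshold when scaled by library size only (edgeR, Benjamini-Hochberg adjusted p = 0.0567, with 6.8e-05 to 0.205 over the alternatives). Camera called the NRF2 list higher (Benjamini-Hochberg adjusted p = 0.0086; adjusted p = 0.74 with an estimated correlation) at a median of 0.38. Of 26 p53 targets 4 rose and 22 were not called, with 5 higher adjusted over the list alone. Camera did not call the list (Benjamini-Hochberg adjusted p = 0.11) and fry called it higher (0.015, and 0.0078 when GC- and length-adjusted). The members that rose were CDKN1A, a cyclin-dependent kinase inhibitor, from 69.1 ± 16.2 to 266 ± 88.8 CPM, PLK3, a kinase, from 16.8 ± 7.73 to 64.6 ± 12.5 CPM, GADD45A, a stress sensor, from 27.8 ± 8.71 to 88.6 ± 1.73 CPM, and TNFRSF10B, a TRAIL receptor, from 192 ± 23.5 to 409 ± 27.8 CPM.

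TNFRSF10B was also the 1 riser among 25 apoptosis regulators, where 24 were not called and 2 were higher and 2 lower adjusted over the list alone; the median was -0.004 while camera pointed upward without a call (Benjamini-Hochberg adjusted p = 0.95). Of 36 lysosome and autophagy genes 3 rose and 33 were not called, with 5 higher and 1 lower adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.11). When GC- and length-adjusted, 7 were higher and 2 lower over all genes. MAP1LC3B, a component of autophagosomes, rose from 68.1 ± 1.71 to 206 ± 14.7 CPM, SQSTM1, an autophagy receptor, from 571 ± 96.7 to 1522 ± 313 CPM, and WIPI1 from 14.7 ± 1.16 to 38.6 ± 5.97 CPM. Among 19 heat shock response genes edgeR called 0, with 1 higher at an unadjusted p under 0.05 and 0 by DESeq2, by limma-voom or adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.17, and 0.031 when GC- and length-adjusted, with 0.026 to 0.74 over the alternatives; adjusted p = 0.38 with an estimated correlation under that adjustment). The median log2 fold change of the heat shock list was -0.25, 14 of the 19 estimates lay below 0, and camera pointed downward. When GC- and length-adjusted, the median was -0.26, and 1 member was called higher and 1 lower over all genes. At an unadjusted p under 0.05 that fit gave 1 higher and 6 lower. HSP90AB1 measured 2807 ± 478 and 3020 ± 340 CPM and HSPA8 1767 ± 494 and 1492 ± 110 CPM. MT1X, whose reads may be shared with other metallothioneins, fell from 20.1 ± 7.67 to 3.34 ± 1.16 CPM and was the 1 called of 5 metallothionein and metal response genes, over all genes and adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.93). That list had a median of 0.03, negative under library size only and upper quartile scaling, while its mean was -0.32 and camera pointed downward.

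Cell cycle lists gave 1 call. E2F2, a transcription factor of S phase entry, fell from 12.8 ± 2.56 to 3.04 ± 1.15 CPM and was the 1 called of 42 S phase and DNA replication genes, with 1 lower adjusted over the list alone and 10 lower when GC- and length-adjusted. Camera called this list lower at a median of -0.20 (Benjamini-Hochberg adjusted p = 0.00061; adjusted p = 0.74 with an estimated correlation), and not without Control replicate 2 or CPI-613 replicate 1, at adjusted p of 0.054 and 0.1. Among 40 G2 and M phase genes edgeR called 0, with 0 at an unadjusted p under 0.05, by DESeq2, by limma-voom and adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.14, and 0.014 without CPI-613 replicate 1). The GC- and length-adjusted fit called 0 of these 40 genes, with 4 lower at an unadjusted p under 0.05. With an estimated correlation and all libraries camera gave an adjusted p = 0.88. MKI67, a proliferation marker, measured 340 ± 70.2 and 186 ± 143 CPM, and CDC20 293 ± 87.2 and 334 ± 113 CPM. Of 11 tested replication-dependent histones edgeR called 0, with 1 higher at an unadjusted p under 0.05 and 0 by DESeq2, by limma-voom or adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.12, and 0.006 without Control replicate 3, with 0.8 at an estimated correlation and all libraries). H2BC12 measured 40.2 ± 4.19 and 59.8 ± 9.32 CPM and H2BC5 15.3 ± 2.17 and 13.8 ± 2.18 CPM. Transcripts of this class mostly lack poly(A) tails, which was not checked for the tested members.

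Growth-related lists held 2 called members. Of 30 MYC targets and ribosome biogenesis genes 2 rose and 28 were not called, over all genes and adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.95). ODC1, the first enzyme of polyamine synthesis, rose from 217 ± 105 to 992.5 ± 185 CPM and MYC from 131 ± 27.3 to 308 ± 34.4 CPM. Among 71 cytosolic ribosomal proteins edgeR called 0, with 0 at an unadjusted p under 0.05, by DESeq2, by limma-voom and adjusted over the list alone. The GC- and length-adjusted fit also called 0 of them, with 3 higher and 1 lower at an unadjusted p under 0.05. RPS2 measured 3102 ± 471 and 4055 ± 1895 CPM and RPLP0 1898 ± 246 and 2342 ± 921 CPM. Camera called the ribosomal list higher at a median of 0.23 (Benjamini-Hochberg adjusted p = 0.03; adjusted p = 0.98 with an estimated correlation), whereas without CPI-613 replicate 3 the median was -0.07 and the list was not called (Benjamini-Hochberg adjusted p = 0.38). Its call also ended without Control replicate 1 or 3, at adjusted p of 0.098 and 0.096, and when GC- and length-adjusted, at 0.24. Scaled by library size only the median was 0.01, and with upper quartile scaling 0.11, and neither was called (camera, Benjamini-Hochberg adjusted p = 0.23 and 0.08, with 1.1e-05 to 0.98 over the alternatives).

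Markers of other cell types held 1 called member. CD14, a monocyte surface receptor, fell from 24.4 ± 6.45 to 2.43 ± 1.79 CPM and was the 1 called of 8 tested leukocyte markers, over all genes and adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.46). PTPRC, expressed by leukocytes in general, had 4 reads in the Control libraries together and 1 in the CPI-613 libraries. Among 5 tested fibroblast markers edgeR called 0, with 0 at an unadjusted p under 0.05, by DESeq2, by limma-voom and adjusted over the list alone; FBLN1 measured 61.8 ± 0.824 and 48.2 ± 16.6 CPM and COL1A1 36.3 ± 3.20 and 34 ± 4.49 CPM. In the GC- and length-adjusted fit 0 fibroblast markers were called over all genes and 1 was lower adjusted over the list alone. At an unadjusted p under 0.05 it gave 2 lower. Camera did not call that list (Benjamini-Hochberg adjusted p = 0.2). Among the alternatives, with an adjusted p of 0.024 to 0.89, it called the list lower without CPI-613 replicate 3 (0.024), also with Control replicate 2 left out (0.037), and when adjusted for GC content alone (0.032). It did so as well when GC- and length-adjusted, with all libraries (0.034; adjusted p = 0.58 with an estimated correlation) and without CPI-613 replicate 3 (0.044). ERG, the 1 endothelial marker above the count filter, measured 1.86 ± 0.489 and 1.40 ± 0.227 CPM, and 0 endothelial markers were called by edgeR, 0 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom.

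The 10 largest rises and falls among genes with a mean log2 CPM of at least 2 reached across several functions. After FGF19 the rises were led by INHBE, an inhibin subunit, with a log2 fold change of 5.11 (SE 0.34), CHAC1, and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, with 3.81 (SE 0.29). ADM2, a peptide hormone, rose by 3.78, UPP1, the uridine phosphorylase, by 3.71, BHLHA15, a secretory cell transcription factor, by 3.60, KIF21B, a kinesin, by 3.39, TNFSF15, a TNF family cytokine, by 3.28, and MSC, a basic helix-loop-helix repressor, by 3.22 on the log2 scale (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p between 0.00387 and 0.0179 for these 10 genes). KRT13 led the falls with a log2 fold change of -7.38 (SE 0.67), followed by ASB2, a ubiquitin ligase subunit, with -3.93 (SE 0.67), and CEMIP, a hyaluronan-degrading protein, with -3.36 (SE 0.46). CD14, DHRS3, a retinaldehyde reductase, TNFSF10, which encodes TRAIL, STC1, a glycoprotein hormone, GBP2, ID3 and CLCA2, a membrane protein of epithelia, had log2 fold changes between -3.32 and -3.10 (edgeR, Benjamini-Hochberg adjusted p between 0.00692 and 0.03 for these 10 genes). CLCA2 missed the threshold with limma-voom (Benjamini-Hochberg adjusted p = 0.0533, with 2.51e-07 to 0.171 over the alternatives).

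Over the 36 lists with at least 3 tested genes camera called 12, 8 higher and 4 lower, and fry called 9. Fry left out the NRF2, S phase, keratinocyte, hypoxia and ribosomal lists (Benjamini-Hochberg adjusted p of 0.18 to 0.79) and added the TGF-beta and p53 lists. With an estimated correlation camera called 0, with 6 lists at an unadjusted p under 0.05 and a smallest adjusted p of 0.11. By edgeR over all genes and GC- and length-adjusted, 9 keratinocyte genes were lower, and 13 NF-kB genes were higher and 4 lower. Matrix genes had 9 higher and 8 lower, TGF-beta genes 6 and 7, fatty acid oxidation genes 5 and 1, p53 targets 6 and 0, apoptosis regulators 4 and 3, checkpoint genes 3 and 3, and thrombospondins and their receptors 2 and 2. When GC- and length-adjusted, camera called 15 lists and fry 12, and with an estimated correlation the ATF4 list was the 1 list called (camera, Benjamini-Hochberg adjusted p = 0.045). The deposited gene table, taken as FPKM (fragments scaled to transcript length and library size), gave log2 fold changes on the log2(FPKM + 1) scale. They correlated across 12501 genes with those of edgeR at a Pearson r of 0.882 and a Spearman rho of 0.947. Genes are not independent replicates. All 398 called genes matched to that table had the same direction there. This is no independent support, since both deposited tables come from the same libraries.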

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

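The GC and length offsets, the pair of libraries left out together, the day-month reading and the settings for the FPKM table were chosen after seeing the data; the other settings were fixed before. With 3 libraries per group, depth limits these results less than the spread between libraries does. Against 403 called genes (246 higher, 157 lower, 397 at least 2-fold), DESeq2's Wald test called 872 (471, 401 and 737), the offset for GC and length 1470 (789, 681 and 798), for GC alone 1301 (708, 593 and 776), and for both without CPI-613 replicate 3 1387 (749, 638 and 802). An adjusted p of 0.01 left 70. Leaving out Control replicate 2 and CPI-613 replicate 3 together gave 737, with 407 lower and 691 at least 2-fold, and moved the share of calls that were higher from 61% to 44.8%. Scaling by library size only gave 259 lower of 488, moved that share to 46.9% and the median of all genes to -0.17. The other 6 settings gave 383 to 414 calls. No called gene changed sign in these settings, or without 1 library and without the offset. The self-test with the observed trends recovered more changed genes once the trend was removed. It added and removed the trend with the same form of loess fit, so it cannot show that the offset suits the real libraries. The cause of these shifts was not tested.

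Leaving out 1 library gave 0 to 905 calls without the offset, with 0 to 467 higher, 0 to 438 lower and 0 to 832 at least 2-fold. With the offset it gave 589 to 2603 calls. Without the offset THBS2 then ranged from -0.96 to -0.73, the number of lists called from 10 to 15, and the medians from -0.13 to 0.16 for TCA enzymes, 0.38 to 0.51 for ER chaperones, 1.22 to 1.55 for the ATF4 list, -0.18 to 0.15 for thrombospondins, 1.36 to 1.47 for cholesterol genes and -1.54 to -1.14 for interferon genes.

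The labels do not say whether a replicate number marks a shared culture or day. The deviations of same-numbered libraries correlated across genes at 0.46, -0.096 and -0.61, and Control 2 correlated best with CPI-613 replicate 3, at 0.68. These values were taken without GC adjustment. Log2 CPM minus the mean of the 6 libraries rose with GC content in Control 2 and CPI-613 replicate 3 (Spearman correlation 0.29 and 0.756). In Control 3 it fell (-0.573). The correlations therefore cannot tell whether the numbers pair the samples. A replicate block gave 191 calls, 109 higher, 82 lower and 191 at least 2-fold, and 12 lists called.

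THBS2 passed the threshold with DESeq2 (-0.84, adjusted p = 0.0189), with the offset for GC and length (-0.93, 0.0146) or GC (-0.95, 0.0293), with the former without CPI-613 replicate 3 (-0.81, 0.0204) and without Control replicate 2 and CPI-613 replicate 3 (-0.89, 0.035). With the offset for GC and length it also passed without Control replicate 2 (-1.05, 0.0133), CPI-613 replicate 1 (-0.95, 0.0176) or CPI-613 replicate 2 (-1.02, 0.0449), and missed without Control replicate 1 (-0.84, 0.0757) or 3 (-0.87, 0.0709). Over all alternatives its adjusted p was 0.0133 to 0.426. With an estimated correlation 0 lists were called and 1 with the offset as well, the ATF4 list; the medians stayed at 0.41 and 0.46 for ER chaperones (adjusted p = 0.25 and 0.26), 1.44 and 1.37 for cholesterol genes (0.11 and 0.29) and -1.40 and -1.24 for interferon genes (0.19 and 0.38), and at 1.42 for the ATF4 list (0.11). The median of complexes III to V ranged from -0.166, without CPI-613 replicate 3, to 0.306 with 1 library left out, and that of ribosomal proteins to -0.0742 without it, -0.0643 with the offset as well and -0.0248 without Control replicate 2 too. Among results that missed the threshold, 133 values, counted over results and settings, had the opposite sign. The correlation with the FPKM table rose to 0.962 with a pseudocount of 0.1 and 0.957 over genes with a mean FPKM of at least 1.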

Other observations

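Gene families outside the fixed lists were looked up after the fits, so their counts describe these libraries and are no independent test. Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation, 5 rose with CPI-613 by edgeR (8 when GC- and length-adjusted): WARS1 from 179 to 628 CPM, GARS1 from 163 to 413, AARS1 from 273 to 703, SARS1 from 110 to 277 and CARS1 from 140 to 313. The other 15 were not called, and TARS1 measured 406 and 398 CPM. Of the 17 mitochondrial synthetases edgeR called 0, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom, and LARS2 measured 38.1 and 37.4 CPM. Their median was 0.0103 and negative, down to -0.157, in other scalings, and whether the families differed was not tested. WARS1, GARS1, AARS1 and SARS1 are also members of the ATF4 list.

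Of 6 tested kallikrein-related peptidases, secreted proteases of epithelia that lie side by side in the genome and are close paralogs, 4 fell and 2 were not called, with KLK10 from 54.6 to 7.94 CPM and KLK8 from 5.99 to 0.966. Of 9 tested genes of retinoid response and handling 4 fell and 5 were not called: DHRS3 from 88.3 to 9.01 CPM, STRA6, a retinol transporter, from 32 to 4.67, CRABP2, a retinoic acid binding protein, from 138 to 27, and PLAAT4 from 5.28 to 0.979. Of 10 tested BMP response genes ID1, ID2, ID3, SMAD6 and ATOH8 fell, HEY1 rose from 0.982 to 4.10 CPM, and 4 were not called, SMAD7 among them at 17.4 and 22.1. These family counts were 5, 5 and 5 lower when GC- and length-adjusted, and these family medians kept their sign in the scalings run. Of 7 EGF receptor ligands HBEGF and AREG rose and 5 were not called, and 4 were higher when GC- and length-adjusted. Reads given to nuclear copies of mitochondrial 16S rRNA may come from the mitochondrial gene itself, which was not tested. Of 7 such copies edgeR called 0, with 0 at an unadjusted p under 0.05, by DESeq2 and by limma-voom. All 7 estimates lay above 0 in that fit, and when GC- and length-adjusted MTRNR2L3 was called higher and 5 had a higher value at an unadjusted p under 0.05.

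The tests of GC content and length on each pattern, and those of depth, of a stronger response and of leukocytes, were chosen or changed after the result was seen. Libraries of one group lay along one axis, with CPI-613 replicates 1 and 3 at its ends. GC content and transcript length accounted for 66.9% of the variance of CPI-613 replicate 3's difference from the mean of the other libraries of its group. This share was 64.2% for CPI-613 replicate 1, 6.16% for CPI-613 replicate 2, and 17.9%, 38.1% and 33.1% for Control replicates 1 to 3. Relative to the mean of the 6 libraries, CPI-613 replicates 1 and 3 followed GC content in opposite directions (Spearman correlation -0.658 and 0.756). Each enters the other's share, so the shares are not separate properties of each library. Against depth as the source, libraries of one group with nearly equal totals differed in how they followed GC content. Their Spearman correlations, taken on deviations from the mean of the 6 libraries, were 0.863 apart for Control 2 and 3 (totals 2.77% apart). They were 0.936 apart for CPI-613 replicates 1 and 2 (totals 3.25% apart). A stronger response in replicate 3 stays open: its difference from replicate 2 correlated across genes at -0.19 with that of CPI-613 replicate 1 from Controls 1 and 3 after adjustment, but replicates 1 and 3 lay at opposite ends of the second adjusted component (-44.3 and 32.1), which enters this value, and replicate 3 lay farthest from Control on the first (21, 35.1 and 46.4 in CPI-613 against -40.5, -20.3 and -41.6). A GC-dependent step in library preparation or sequencing may contribute to the axis.

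For the fall of interferon-stimulated genes, the median log2 fold change was -1.40 before and -1.24 after adjustment, which argues against GC content and length as the whole source. Members called went from 11 to 28, but calls over all genes also went from 403 to 1470, so this count does not bear on the source. Without CPI-613 replicate 3 the median was -1.29, so this library alone does not carry it. Leukocytes in the control cultures would bring PTPRC, whose Control mean of 0.11 CPM, here on unscaled library totals, was 0.055% of the 200 CPM that the 11 called members lost together. Of myeloid markers CD14 (945 reads in Control and 96 with CPI-613), CSF1R (110 and 60) and ITGAM (70 and 44) had more reads in Control. CD68 had 1949 and 2182 reads (53.9 and 50.3 CPM), ITGAX 43 and 41, LYZ 38 and 36 and FCER1G 2 and 3. CORO1A (2427 and 3348) and LCP1 (146 and 293) had fewer in Control. These reads are not scaled, and the CPI-613 libraries were deeper. An earlier bound on PTPRC, CORO1A and LCP1, each below 1 CPM, was replaced because it did not allow for carcinoma cells that express them. What lowers these genes stays open, and reads shared between paralogs such as IFITM1, IFITM2 and IFITM3 were not tested.

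The rise of ATF4 target genes is the third. After GC and length adjustment the median was 1.22, and without CPI-613 replicate 3 it was 1.22, against either as the whole source. Members called went from 21 to 33 with the adjustment, which does not bear on this, since calls over all genes went from 403 to 1470. Of 10000 random lists matched on GC content and mean expression none reached the list's 1.42, and the highest was 0.391, against a general rise of such genes. A stress response to CPI-613 is consistent with these values, as a hypothesis found and tested on the same libraries.

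The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share of splits under 0.1. The real split called 403 genes and 1 of 10 splits, the real one, called as many, with 0 as the highest of the others by edgeR; with GC and length adjustment these were 1470, 1 and 0. The split of Control 1, Control 3 and CPI-613 replicate 1 against the rest, which follows the GC axis, gave 4690 genes at an unadjusted p under 0.05 against 1823 for the real split and 2418 calls by DESeq2 against 872, which points to a structure of the samples besides the groups. With adjustment its 4690 became 2423 against 3273 for the real split.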
